A study of Homo sapiens with 10 samples.

How the data were processed

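Peripheral blood mononuclear cells (PBMC) of 10 donors were profiled on the Illumina HumanHT-12 beadchip, 1 array per donor. Groups were taken from the infection label of each sample, which gave 5 donors with chronic hepatitis C virus (HCV) infection sampled before therapy and 5 healthy volunteers. Replicate numbers were given in accession order within a group and only name a sample. Per the labels' protocols, cells were separated from whole blood on a Ficoll density gradient, total RNA was extracted with a column kit and checked by absorbance and electrophoresis, and labelled RNA was hybridised by a core facility with the standard Illumina procedure. No slide, position, scan date, extraction batch or processing step after scanning is given in the sources used here, so no batch could be tested.

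The deposited non-normalized table held, for each of 47323 probes and each array, a log2 intensity and a detection p-value, per the file headers and the values. The log2 scale was found from the values: 96.4% of the deposited values below a linear intensity of 1000 came back to a number with 4 decimals, within 0.05 of the last decimal, when raised as a power of 2. The design written beforehand had assumed linear intensities, so the values were taken back to that scale before background correction. Detection p-values, as deposited, moved in steps of about 1 in 770, the step that a set of negative control beads of that size gives. The deposited series matrix held a second set of log2 values of the same arrays, each column with the same distribution (median 6.91, largest spread between columns at one rank 0.00577), which lay a mean of 0.0771 from the average distribution of the 10 arrays. Its log2 scale was found by comparison with the other table. Its normalization target is not given in the sources used here.

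The deposited tables disagree on which arrays are HCV. Columns of the non-normalized table carry the code that ends a sample title, and each code matched a single sample. Columns of the series matrix carry the sample record itself. Compared by ranks, each series matrix column was identical to an array that the other table gives to the opposite group (rank correlation 1 in 10 of 10 columns), and no column matched the array of its own name (highest correlation with it 0.897). The group of an array was taken from the column name of the non-normalized table, before any difference between groups was looked at. The series matrix as deposited was kept as an alternative for the genes named by the rule, the lists and 2 scores.

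Linear intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp background correction with control information inferred from the detection p-values, offset 16, quantile normalization between arrays, log2). Probes with a detection p-value under 0.05 on at least 5 of the 10 arrays, whatever their group, were kept (18404 probes). Gene names came from the platform annotation supplied for the probes: 30113 probes had 1 gene symbol, 8 had several and 17202 were unnamed here. Symbols of 30074 probes were checked through their gene identifiers against RefSeq genes of assembly GRCh38.p14, which was used for names only. Each gene was represented by its kept probe with the highest mean over all 10 arrays, giving 10717 genes, of which 2687 had over 1 kept probe. Tables were read with the data.table package (1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

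Gene differences were tested with limma (lmFit and eBayes with the default prior, no covariates, two-sided) and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The 23 gene lists fixed before the data were examined, 9 of them cell type markers, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. A list was tested when at least 5 members were measured. The score of a donor for a list is the mean log2 value of its measured members, and scores were compared by an exact two-sided permutation test over all 252 assignments of the donors, whose smallest possible p is 0.00794. A probe not detected on any array of 1 group has only a bound there: its fold is given as at least the brighter group's mean against, per array, the higher of the probe's own signal and the lowest signal of any detected probe. Means are given with SD and n = 5 donors per group, and the number of arrays limits the precision.

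Genes were named by a rule fixed beforehand. It took up to 12 genes per direction past the threshold with the largest difference among those whose groups do not overlap, then up to 6 members of each list past the threshold or, where none passed, the 2 with the smallest p, and 19 genes given whatever their values. Of these 19, 1 is unnamed here and 2 did not pass the detection filter. Sex-linked genes, genes whose signal mainly follows a common germline deletion or haplotype, genes with only a locus number and unnamed probes were excepted from naming and stayed in the counts.

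The scripts were tested on simulated data for this comparison over 10717 genes. Of 50 genes changed at each size, 16% were recovered at a log2 change of 0.5, 72% at 1, 98% at 1.5 and 100% at 2, with 5 false calls in all. In a simulated test of the lists, 1 list shifted by 0.5 was called and 0 of the 22 other lists were. Simulated genes were drawn independently of each other. Neither simulation can therefore show the false calls that arise where genes of a list vary together. Alternatives covered background correction, scaling, the source of the values, the dim-probe filter, the handling of several probes per gene, the variance model, array weights, rank tests, thresholds, list tests, score definitions and leaving out each donor in turn. The array slide as a block was planned and not run.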

Results

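PBMC, the lymphocytes, monocytes and associated cells left after density separation of blood, were compared between 5 donors with untreated chronic HCV infection and 5 healthy volunteers to see which transcripts differ in blood during chronic infection. Between 34.9% and 41.9% of the probes of an array were detected, with a mean of 38.5% ± 2.16 in HCV and 40.6% ± 1.57 in healthy donors (SD, n = 5; exact permutation p = 0.119). The spread of raw log2 intensities over probes was narrower in HCV (SD over probes 1.14 ± 0.0354 against 1.22 ± 0.0620, n = 5; exact permutation p = 0.0476). Normalized arrays correlated at 0.955 to 0.986. All differences are HCV minus healthy with groups read from the column names of the non-normalized table. The deposited series matrix holds the same arrays under the opposite group. Of the values run under it (genes named by the rule, lists and 2 scores), the signs are the reverse there, apart from the medians of the CD8 and neutrophil lists, and the direction is not settled between the tables.

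In HCV, single transcripts of viral RNA sensors, granulocytes, red cells and B cells rose, and a group of small nucleolar RNAs fell. ALPL, the alkaline phosphatase of mature neutrophils, was 7.44-fold higher (95% interval 3.36 to 16.5; detected in 3 healthy donors, so that the background limits its size), PROK2, a secreted chemoattractant, 3.12-fold (2.09 to 4.66) and FPR2, a formyl peptide receptor, 2.91-fold (2.10 to 4.02). HBA1, alpha globin, rose 2.66-fold (1.80 to 3.94) and SLC25A37, the mitochondrial iron carrier, 2.66-fold (1.82 to 3.89). CD79A, a chain of the B cell receptor complex, was 2.24-fold higher (1.63 to 3.08) by its brightest probe, while its 3 probes gave log2 differences of 0.31 to 1.16. The viral RNA sensors RIGI and IFIH1 rose 1.92-fold (1.58 to 2.33) and 1.79-fold (1.44 to 2.23), and the interferon receptor chain IFNAR1 1.58-fold (1.31 to 1.89). Among genes past the threshold and detected in both groups, the largest falls were in TNNC2, a troponin of fast muscle, with a log2 difference of -1.65 ± 0.31 (SE), the Y RNA RNY5 (-1.20 ± 0.19) and SCARNA9 (-1.18 ± 0.19). The background also limits TNNC2, RNY5, SNORA72 and SNORA27, detected in 3 HCV donors, and TNFAIP6, detected in 3 healthy donors.

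Of 10717 genes, 15 were higher and 24 lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and the median difference of all genes was 0.02. The adjusted p of the named genes that passed lay between 0.0109 for SNORA72 and 0.0497 for OSBPL10. At an unadjusted p under 0.05 there were 906 higher and 786 lower genes, and at an adjusted p under 0.1 there were 94 and 120. In 449 genes (4.19% of those tested, against 0.794% by chance) the values of both groups did not overlap, and this held for 38 of the 39 genes past the threshold, ALPL being the exception. The other named genes past the threshold were PARP9 (1.06 ± 0.20), OSBPL10 (0.94 ± 0.18), a lipid-binding protein, TP53RK (0.70 ± 0.13) and OTULIN (0.68 ± 0.13), a deubiquitinase of linear ubiquitin chains, all higher. Lower were KLHL15 (-0.94 ± 0.14, detected in 1 HCV donor, so that the background limits its size) and the pseudogene HTATSF1P2 (-0.99 ± 0.17), whose probe could also read its parent gene. HMGCLL1 and CD70, named after their values were seen, complete the 15 higher genes. Scaling the arrays by their medians in place of quantiles gave 8 higher and 178 lower genes, with the median of all genes moved to -0.20. Without background correction 0 genes passed, with 1731 at an unadjusted p under 0.05. Leaving out healthy replicate 1, 2, 3 or 5 left 2, 0, 6 and 2 genes past the threshold. Leaving out HCV replicate 1, 2, 3, 4 or 5 left 21, 8, 2, 14 and 5, and 44 passed without healthy replicate 4. In 5 of the 10 cases (without healthy replicate 1, 2 or 5 or HCV replicate 3 or 5) 0 genes were higher.

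**Figure D1:**
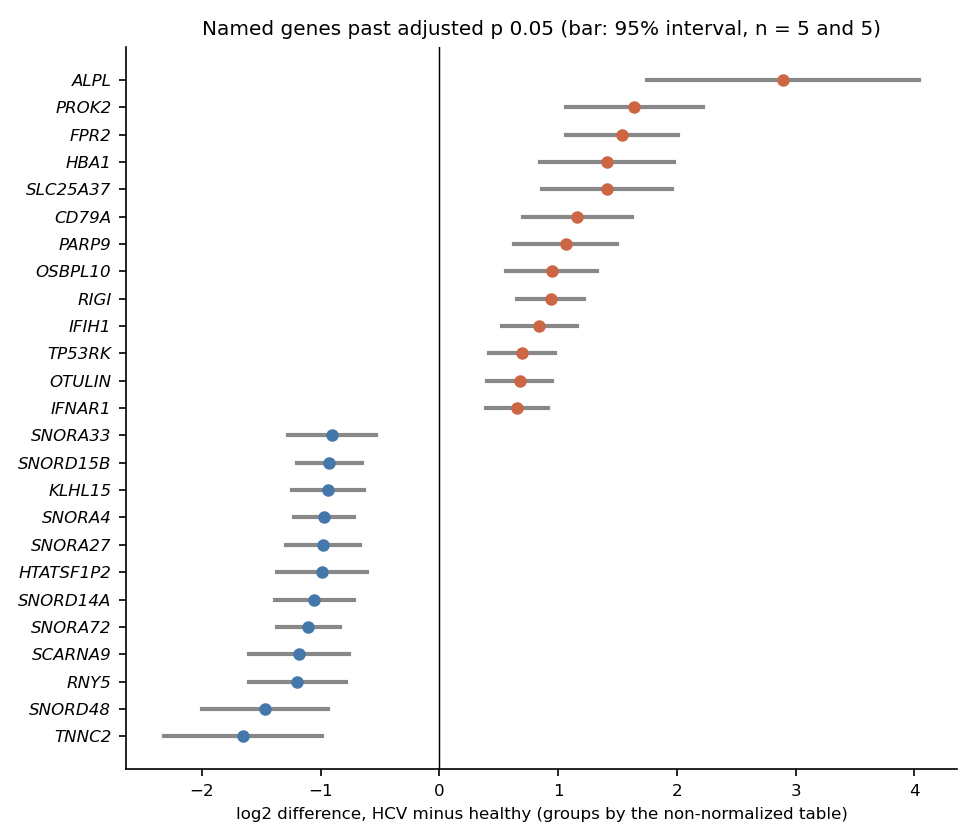
Log2 difference (HCV minus healthy, groups by the non-normalized table, reversed in the series matrix) of the 25 named genes past an adjusted p of 0.05, as points with 95% intervals from limma (n = 5 and 5). The 13 higher genes run from IFNAR1 (0.66) to ALPL (2.90) and the 12 lower from SNORA33 (-0.90) to TNNC2 (-1.65). SNORA4 and SNORD48, not detected in any HCV donor, have only a bound on their fold, and their points show the fitted difference.

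Type I interferon-stimulated genes, the antiviral programme switched on by interferon alpha and beta, shifted upward in HCV as a list. Of 56 measured members of 62, 55 had a positive difference, with a median of 0.66, and RIGI, IFIH1 and PARP9 passed the threshold over all genes. Adjusted over the list alone, 26 members were higher and 0 lower. The list passed camera (adjusted p = 1.53e-18) but not with an estimated correlation (adjusted p = 0.392 with an estimated correlation, which was 0.512). The score was 9.24 ± 0.52 in HCV and 8.52 ± 0.25 in healthy donors (SD, n = 5; difference 0.72, exact permutation p = 0.0159, adjusted over lists 0.0730). HCV donors differed widely, from 8.74 to 10.11 in HCV replicate 5, and without that donor the difference was 0.50. Under median scaling it was 0.47 with an exact permutation p of 0.0952.

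Of 7 members named whatever their values, 0 passed the threshold, although MX1, IFIT1, RSAD2, IFI44L and IRF7 lay above the healthy median in all 5 HCV donors and OAS1 and ISG15 in 4. Log2 differences (limma adjusted p in brackets) were 1.31 for MX1 (0.0751), 2.09 for IFIT1 (0.135; its 2 probes gave 0.50 and 2.09), 1.52 for RSAD2 (0.168), 1.71 for IFI44L (0.242), 0.85 for IRF7 (0.236), 0.60 for OAS1 (0.353) and 0.66 for ISG15 (0.544). IFI27 was not detected in any healthy donor and was detected in 4 of 5 HCV donors, at least 2.55-fold higher by the group means. The HCV mean rests largely on HCV replicate 5 (9.23, against 4.71 to 6.20 in the other HCV donors, SD 1.71 with n = 5). The bound therefore does not hold for each HCV donor. USP18 was detected in 1 healthy and 3 HCV donors and was not tested.

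Related lists moved the same way. Interferon ligands, receptors and signalling genes had 14 of 19 members positive (median 0.29), 1 past the threshold (IFNAR1) and 5 adjusted over the list alone. Camera gave an adjusted p of 0.00100 (0.269 with an estimated correlation), and it was the single list of 23 past fry (adjusted p = 0.00640). Its score was 9.20 ± 0.097 in HCV and 8.91 ± 0.049 in healthy donors (SD, n = 5), with no overlap and an exact permutation p of 0.00794, the smallest possible. Interferon-gamma-associated genes were positive in 22 of 24 members (median 0.35; camera adjusted p = 8.00e-06, 0.421 with an estimated correlation). Of these, 0 passed the threshold and 1 when adjusted over the list alone, and the smallest p was in GBP1 (0.89, adjusted p 0.102) and FCGR1BP (0.94, 0.152), whose probes could read paralogs. CXCL10, an interferon-induced chemokine, differed by 1.27 (adjusted p 0.239). Nucleic acid sensing genes were positive in 13 of 16 (median 0.30; camera adjusted p = 0.00100, 0.392 with an estimated correlation). Of these, 0 passed the threshold and 6 when adjusted over the list alone, and the smallest p was in TUT7 (0.74, adjusted p 0.0722) and TRIM25 (0.79, 0.0889). Genes of MHC class I antigen presentation were positive in 17 of 18 (median 0.22; camera adjusted p = 0.00161, 0.421 with an estimated correlation). Among them 0 passed the threshold and 1 did when adjusted over the list alone, with values of 0.59 in TAP1 (adjusted p 0.109) and 0.29 in PSMB10 (0.279). Under median scaling the median of this list was -0.069 (all genes -0.20) and it did not pass (camera adjusted p = 0.173).

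**Figure D2:**
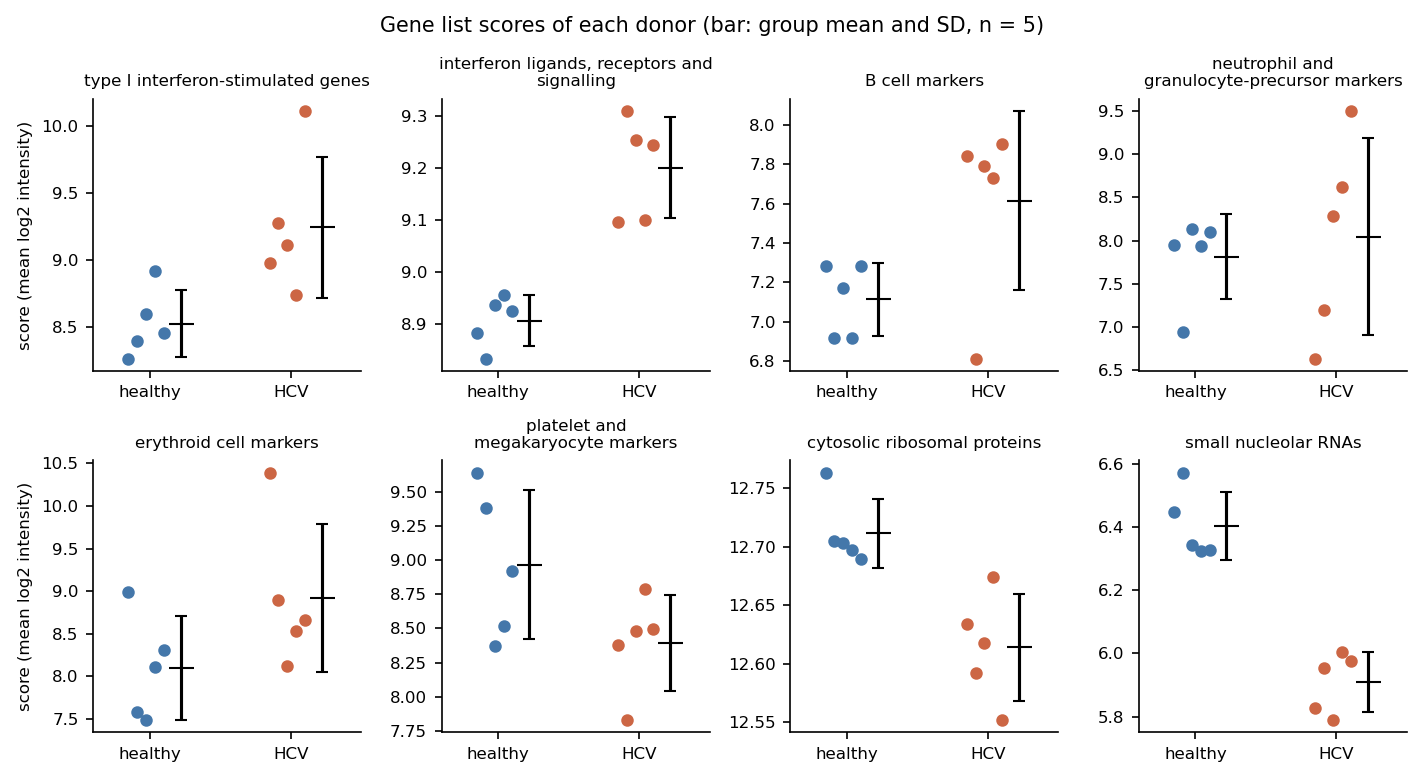
Score of each donor (mean log2 intensity of a list's measured members, 1 point per donor) for 7 fixed lists and the small nucleolar RNAs, with group mean and SD (n = 5) and groups by the non-normalized table. Interferon signalling and ribosomal protein scores and those of small nucleolar RNAs do not overlap between groups, and HCV replicate 2 lies apart from the other HCV donors in B cell markers (6.81 against 7.73 to 7.90).

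Lists of markers of 4 blood cell types passed camera at the preset correlation, and their scores overlapped between groups (exact permutation p 0.0794 for platelet, 0.0556 for B cell, 0.111 for erythroid and 0.325 for monocyte markers, n = 5 and 5). All 28 measured platelet and megakaryocyte markers had a negative difference (median -0.58; camera adjusted p = 1.17e-09, 0.421 with an estimated correlation). The threshold was passed by 0, and by 3 when adjusted over the list alone, with values of -0.98 for SPARC (adjusted p 0.0757), -0.90 for NRGN (0.0979) and -0.58 for PPBP (0.399). B cell markers were positive in 23 of 23 members (median 0.42; camera adjusted p = 6.85e-08, 0.421 with an estimated correlation). CD79A passed the threshold and 8 members were higher adjusted over the list alone, with a difference of 0.35 in MS4A1 (adjusted p 0.404). Erythroid markers were positive in 17 of 21 (median 0.61; camera adjusted p = 1.70e-05, 0.421 with an estimated correlation). HBA1, whose probe could also read HBA2, passed the threshold and 2 members did when adjusted over the list alone, with HBB at 0.33 (adjusted p 0.334). HBB lay at 14.33 to 14.45 in HCV and HBA1 at 13.89 to 14.37, where the highest value of any gene was 14.59, so the signal range limits both differences. HCV replicate 1 had the highest erythroid score (10.39). Monocyte markers were positive in 25 of 33 (median 0.17; camera adjusted p = 0.0199, 0.727 with an estimated correlation). Past the threshold were 0, and 1 adjusted over the list alone, with values of 0.99 in CCR2 (adjusted p 0.0751), 0.81 in TLR4 (0.164) and 0.39 in CD14 (0.255). The median of the monocyte list was -0.11 under median scaling.

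Neutrophil and granulocyte-precursor markers did not pass as a list (camera adjusted p = 0.0607, 0.727 with an estimated correlation, with p under 0.05 in 14 of the alternatives at the preset correlation, the series matrix values counted under both groupings) although FPR2, PROK2 and ALPL passed singly and 8 of 27 members were higher adjusted over the list alone. Their median was -0.10, their mean 0.23 and camera's direction upward, and HCV donors ranged from 6.64 to 9.49 in score. FCGR3B, an Fc receptor of neutrophils, differed by 2.59 (limma adjusted p 0.0828) with its brighter probe and by 0.54 with the other, and the 2 probes could also read FCGR3A.

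T cell markers (13 of 27 positive, median -0.04; camera adjusted p = 0.398), CD8 and cytotoxic lymphocyte markers (18 of 35, median 0.01, mean -0.01; 0.727), dendritic cell markers (8 of 18, median -0.04; 0.193) and plasma cell markers (7 of 13, median 0.11; 0.416) did not pass, and 0 of their members passed over all genes. Adjusted over each list alone, 1 dendritic cell marker was lower and 1 plasma cell marker higher. Differences (limma adjusted p in brackets) were -0.38 in CD3E (0.285), 0.44 in SIT1 (0.258), 0.28 in CD8A (0.702), -0.09 in GNLY (0.907), 0.70 in CX3CR1 (0.264) and 0.30 in FCGR3A (0.269; its 2 probes gave -0.10 and 0.30, and the one used was detected in 2 healthy donors). In dendritic and plasma cell markers they were -0.83 in SERPINF1 (0.0618), -0.91 in FLT3 (0.172), 0.55 in POU2AF1 (0.0968) and 0.32 in PRDM1 (0.429, with probes from -0.24 to 0.32). SERPINF1 and FLT3 were each detected in 1 HCV donor, so that the background limits their size. The list of T cell activation and inhibitory receptors passed, with 17 of 20 positive (median 0.31; camera adjusted p = 0.000189, 0.269 with an estimated correlation). Its members included 0 past the threshold and 3 adjusted over the list alone, with values of 0.68 in the transcription factor BATF (adjusted p 0.0697) and 0.66 in the follicular homing receptor CXCR5 (0.0751), which B cells also carry.

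**Figure D3:**
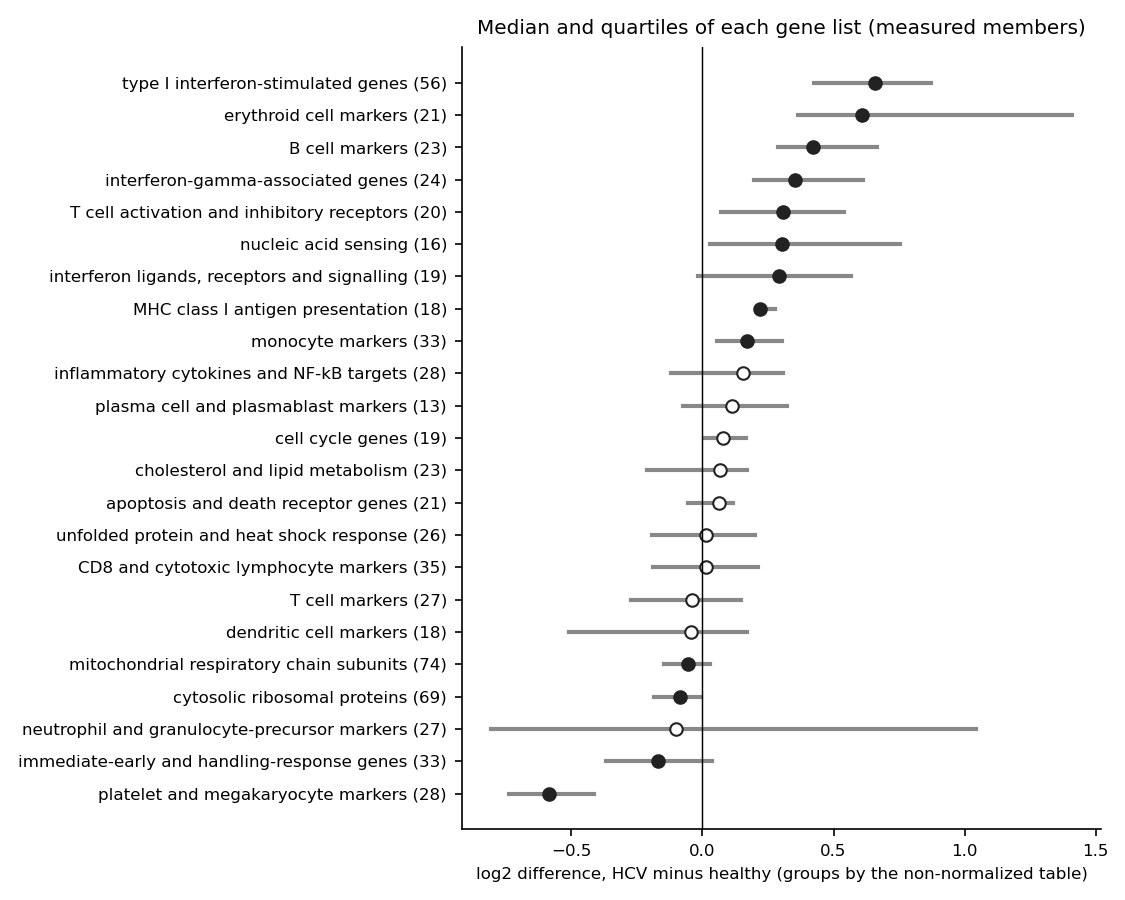
Median (point) and quartiles (bar) of the log2 difference, HCV minus healthy, over the measured members of each of the 23 lists, with groups by the non-normalized table and signs reversed in the series matrix, apart from the CD8 and neutrophil lists. Filled points mark the 13 lists past camera at a preset correlation, from platelet markers (-0.58) to type I interferon-stimulated genes (0.66); 0 lists pass with an estimated correlation.

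Small nucleolar and Cajal body RNAs, which guide the chemical modification of ribosomal and spliceosomal RNAs, made up 14 of the 24 lower genes by the symbols of their probes. Whether these probes read the mature RNAs or transcripts of the genes that host them was not tested. Of 94 measured, 88 had a negative difference (median -0.50), in a class chosen after the called genes were seen. Without the 14 called ones, 74 of 80 were negative (median -0.40). Without a filter on dim probes the class had 301 members and a median of -0.064. With detection p under 0.01 on all arrays it had 38 members and a median of -0.56. Their score was 0.49 lower in HCV (5.91 ± 0.095 there, SD, n = 5; healthy SD 0.11). The groups did not overlap (exact permutation p = 0.00794), a direction kept under median scaling and cyclic loess. Without background correction the score difference was -0.24 and the class median -0.21. Log2 differences with SE were -1.11 ± 0.12 for SNORA72, -1.05 ± 0.15 for SNORD14A, -0.98 ± 0.14 for SNORA27, -0.93 ± 0.12 for SNORD15B (detected in 1 HCV donor, with the same limit) and -0.90 ± 0.17 for SNORA33. SNORA4 and SNORD48 were not detected in any HCV donor and were at least 1.61-fold and 1.99-fold lower there. Cytosolic ribosomal protein genes, several of which host such RNAs, were negative in 54 of 69 (median -0.09; camera adjusted p = 0.000119, 0.421 with an estimated correlation). Past the threshold or adjusted over the list alone were 0, with values of -0.45 in RPL22 (adjusted p 0.155) and -0.50 in RPL7 (0.170). Their score did not overlap between groups (12.61 ± 0.046 against 12.71 ± 0.030, SD, n = 5; exact permutation p = 0.00794, adjusted over lists 0.0730).

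**Figure D4:**
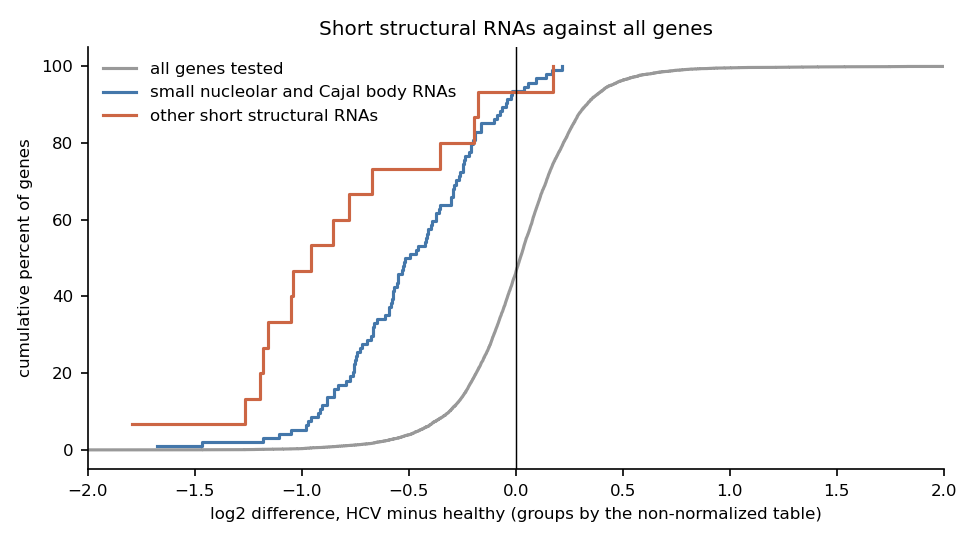
Cumulative percent of genes by log2 difference, HCV minus healthy (groups by the non-normalized table), for all genes tested, 94 small nucleolar and Cajal body RNAs and 15 other short structural RNAs; the x axis ends at -2 and 2. The medians are 0.02, -0.50 and -0.96.

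Among the remaining lists, immediate-early and handling-response genes were positive in 11 of 33 (median -0.17; camera adjusted p = 0.0261, 0.499 with an estimated correlation), with values of -0.58 in GADD45A (adjusted p 0.0751) and 0.31 in KLF2 (0.252). Mitochondrial respiratory chain genes were positive in 27 of 74 (median -0.05; camera adjusted p = 0.00429, 0.421 with an estimated correlation), with values of -0.41 in UQCRHL (0.106), a retrocopy whose probe could read UQCRH, and -0.39 in ATP5F1C (0.140). Lists that did not pass camera were inflammatory cytokines and NF-kB targets (17 of 28 positive, median 0.16; adjusted p = 0.285; TNFAIP6 1.13 with 0.0751, TNFAIP3 -0.75 with 0.140) and cell cycle genes (14 of 19, median 0.08; 0.345; PTTG1 0.47 with 0.238, UHRF1 0.36 with 0.310). The same held for apoptosis genes (15 of 21, median 0.06; 0.345; TNFSF10 0.73 with 0.0979, FAS 0.50 with 0.270). The unfolded protein and heat shock list (14 of 26, median 0.01; 0.658; HSPA6 0.96 with 0.0751, HSPA1A 0.73 with 0.123) and cholesterol and lipid genes (13 of 23, median 0.07; 0.507; ABCA1 0.93 with 0.0817, ABCG1 0.83 with 0.130) did not pass either. In these 7 lists 0 members passed over all genes; adjusted over the list alone, 1 immediate-early gene was lower and 1 inflammatory, 3 unfolded protein, 3 lipid and 1 apoptosis gene were higher. Over all 23 lists, 9 were higher and 4 lower by camera, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05), and 0 scores passed the exact permutation test after adjustment (6 before it). The smallest possible p of that permutation test is 0.00794, so 1 score alone could not pass after adjustment over 23 lists. Of 100 splits of the donors into 5 and 5, 16 gave at least 13 lists past camera, the real one included.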

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

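In this part, the tests of column order, low signal, scaling, short RNA recovery, monocyte share and neutrophil carry-over were chosen only after the result was seen, while leaving out each donor was planned and its reading for HCV replicate 5 was written after its value was seen. A donor was singled out where its gap to the nearest other donor of its group exceeded 0.71 of the range of that group of 5. This held for 12 of 210 groups of values tested, against 10.5 that chance gives, so the pattern of such donors as a whole does not exceed chance.

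Among list scores, HCV replicate 2 lay low in B cell markers (6.81 against 7.73 to 7.90 in the other HCV donors). Healthy replicate 2 lay low in neutrophil markers (6.95 against 7.94 to 8.14) and high in the unfolded protein and heat shock list (9.31 against 9.14 to 9.17). Healthy replicate 1 lay high in ribosomal proteins (12.76 against 12.69 to 12.71). Among named genes, healthy replicate 4 stood apart in SNORD15B (5.56 against 5.98 to 6.14) and FPR2 (7.42 against 6.23 to 6.54), healthy replicate 3 in KLF2 (13.01 against 12.53 to 12.65) and healthy replicate 2 in UHRF1 (5.74 against 5.98 to 6.08). In the HCV group, replicate 1 stood apart in SNORD48 (5.01 against 4.46 to 4.55) and FCGR3A (5.63 against 5.14 to 5.26), replicate 3 in HBA1 (13.89 against 14.26 to 14.37) and replicate 5 in RSAD2 (9.31 against 6.27 to 7.11). Of 4352 tested probes that are unnamed here or carry several symbols, which enter no gene comparison, 18 passed the threshold over 18404 probes (limma), 2 higher and 16 lower in HCV.

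The number of genes past the threshold is hard to obtain by chance, and the number of lists is not. Of 100 splits of the donors drawn from 126, the real one included, 1 called at least 39 genes. The highest of the other splits called 20, so chance is unlikely to give this number but is not excluded. At least 13 lists passed camera in 16 of the 100 splits, and the highest of the others gave 15, so chance is not excluded for the number of lists. The splits other than the real one gave a median of 9 lists past camera.

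The genes named by the rule, the lists and the 2 scores have the opposite sign in the other deposited table, apart from the medians of the CD8 and neutrophil lists. All 10 series matrix columns hold the array that stands at the same place in the column order of the non-normalized table, as it would if series matrix values were placed in the column order of the non-normalized table and not by sample name. The same match would arise if the sample titles, not the matrix values, were out of place. Each title holds both the group and the code, so moving whole titles would leave each code with its group. The direction would reverse if codes were paired with the wrong group within the titles. It would also reverse if the column names of the non-normalized table stood over arrays kept in series matrix order. No measured value tells which, so the direction of every result rests on the column names of the non-normalized table.

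Small nucleolar RNAs were lower in HCV, with a median difference of -0.50 over 94 genes. Low signal in general is argued against as the whole cause. The median of 10000 random gene sets matched on mean level lay between -0.05 and 0.07 in 95% of draws, against -0.505. The class was chosen after its called members were seen. Without those the median of the 80 others was -0.404, for which no matched sets were drawn. Without a filter on dim probes the median of 301 members was -0.064, and with detection p under 0.01 on all arrays that of 38 members was -0.56. Scaling of arrays whose signal ranges differ is also argued against as the whole cause, because relative to each array's median over all genes the score stayed lower in HCV with no overlap under quantile scaling, median scaling and cyclic loess, the smallest difference being -0.442 (and -0.253 without background correction, which is no test of scaling). A lower recovery of short RNAs in the HCV extractions may contribute: 14 of 15 other short structural RNAs (spliceosomal, Y and similar RNAs) were negative, with a median of -0.956 against -0.14 to 0.17 in matched sets. Extraction batches are not given, so recovery and a change in the cells of HCV donors both stay open.

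Type I interferon-stimulated genes were higher in HCV, by 0.72 in score. The interferon-stimulated score minus the monocyte score of the same donor was 0.524 higher in HCV (exact permutation p = 0.0238, n = 5 and 5). This cannot decide on a larger share of monocytes, because it assumes that both scores rise equally with that share. Monocyte markers are brighter (healthy score 10.68 against 8.52), so an equal rise is not given. The subtraction was also not run without HCV replicate 5, which had the highest interferon-stimulated score (10.11). HCV replicate 5 alone is argued against as the whole cause of the plain score difference, which was 0.503 without it (exact permutation p = 0.0317, n = 4 and 5). Neutrophil carry-over stays open, because the score minus the neutrophil score differed by 0.486 with an exact permutation p of 0.325 (n = 5 and 5) and the neutrophil markers went both ways. The infection itself also stays open, untested by any value here.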

How the results depend on the processing

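Alternatives marked here as added, and every value of the small nucleolar RNA score, were chosen after seeing the data; the others were fixed before the data were examined. The number of genes past the threshold depended strongly on the processing. Higher and lower genes numbered 0 and 0 without background correction (1731 at an unadjusted p under 0.05), 1 and 2 with normexp without control information, 2 and 3 with a neqc offset of 50, 8 and 178 with median scaling, 3 and 2 with the series matrix as deposited, 2 and 3 with its values given to the arrays of the same ranks (added). They numbered 3 and 10 without a filter on dim probes, 2 and 1 with detection p under 0.01 on all arrays, 4 and 11 with trend and robust variance, 24 and 30 with array weights and 21 and 50 over probes in place of genes. Thresholds alone moved them to 94 and 120 (adjusted p under 0.1) and 906 and 786 (unadjusted p under 0.05). The exact Wilcoxon test called 0 and 0 (1232 genes at an unadjusted p under 0.05). Its smallest possible p in this design is 0.00794, reached by 449 genes, which gave a smallest adjusted p of 0.189. That floor, and not only the processing, limits its calls. Leaving out each donor gave 0 to 15 higher and 0 to 29 lower genes, with 0 in all without healthy replicate 2 (1486 at an unadjusted p under 0.05). Of the 39 genes, 36 were also called with cyclic loess and 36 with the mean of probes, 35 with array weights, 28 with median scaling, 25 without healthy replicate 4 and 0 to 15 under each other setting that refitted the genes. Except where the test or the number of genes or donors differs by construction, the cause was not tested. Of the lists, 11 to 14 passed camera under each setting with a preset correlation, while 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and 1 passed fry. With the groups of the non-normalized table, the interferon-stimulated score difference stayed between 0.50 and 0.91 with an exact p of at most 0.0397, and was 1.10 in units of SD as a mean of z-scores. Under median scaling it was 0.47 with an exact p of 0.0952. Leaving IFI27 out of the list changed nothing, since it did not pass the detection filter. Median scaling moved the median of all genes to -0.20, and relative to each array's median over all genes the difference was 0.69 (exact p = 0.0159). The small nucleolar RNA score difference stayed between -0.66 (median scaling) and -0.18 (no filter on dim probes, where the median of 301 members was -0.064) with groups by the non-normalized table, with no overlap of the groups under any alternative. Without background correction the difference was -0.24 against -0.49. Signal over background limits SNORA4 and SNORD48 to a bound, since neither was detected in HCV. The array slide as a block was not run, since no slide is given in the sources used here. The neutrophil list (camera adjusted p = 0.0607 as reported, 0.727 with an estimated correlation) had an adjusted p under 0.05 in 14 alternatives at the preset correlation, down to 4.02e-06 under median scaling and 6.05e-05 without HCV replicate 1, and up to 0.766 in the others. These 14 count the series matrix values under both groupings, with the same camera adjusted p of 0.0385. Some alternatives also brought lists reported as not passing under an adjusted p of 0.05 by camera. The lowest values were 0.0120 for inflammatory cytokines and NF-kB targets, 0.0207 for dendritic cell markers and 0.0216 for T cell markers. No setting that keeps the groups of the non-normalized table reversed any of the 25 named genes past the threshold.

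With the series matrix as deposited, where each array carries the opposite group, the signs of the genes named by the rule, the lists and the scores were the reverse of those reported, apart from 2 lists. The interferon-stimulated score difference was -0.56 and the small nucleolar RNA score difference 0.27. Median log2 differences of lists were -0.51 for type I interferon-stimulated genes, -0.25 for interferon-gamma-associated genes, -0.17 for MHC class I antigen presentation, -0.24 for interferon ligands, receptors and signalling, -0.25 for nucleic acid sensing and -0.11 for inflammatory cytokines and NF-kB targets. They were 0.14 for immediate-early and handling-response genes, 0.032 for T cell markers, -0.27 for B cell markers, -0.040 for plasma cell and plasmablast markers, -0.14 for monocyte markers, 0.044 for dendritic cell markers. They were 0.45 for platelet and megakaryocyte markers, -0.52 for erythroid cell markers, -0.23 for T cell activation and inhibitory receptors, -0.033 for cell cycle genes, -0.013 for unfolded protein and heat shock response, -0.036 for cholesterol and lipid metabolism, -0.041 for apoptosis and death receptor genes, 0.089 for cytosolic ribosomal proteins and 0.041 for mitochondrial respiratory chain subunits. Log2 differences of genes there were ABCA1 -0.67, ABCG1 -0.52, ALPL -1.80, ATP5F1C 0.33, BATF -0.50, CCR2 -0.88, CD14 -0.38 and CD3E 0.34. CD79A -0.98, CD8A -0.24, CX3CR1 -0.60, CXCL10 -0.88, CXCR5 -0.52, FAS -0.22, FCGR1BP -0.82 and FCGR3A -0.11. FCGR3B -1.95, FLT3 0.40, FPR2 -1.09, GADD45A 0.42, GBP1 -0.80, GNLY 0.077, HBA1 -1.31 and HBB -0.43. HSPA1A -0.65, HSPA6 -0.84, HTATSF1P2 0.48, IFI44L -1.40, IFIH1 -0.69, IFIT1 -1.65, IFNAR1 -0.54 and IRF7 -0.70. ISG15 -0.54, KLF2 -0.24, KLHL15 0.37, MS4A1 -0.25, MX1 -1.05, NRGN 0.76, OAS1 -0.53 and OSBPL10 -0.59. OTULIN -0.47, PARP9 -0.95, POU2AF1 -0.36, PPBP 0.45, PRDM1 -0.28, PROK2 -1.43, PSMB10 -0.23 and PTTG1 -0.37. RIGI -0.51, RNY5 0.55, RPL22 0.37, RPL7 0.42, RSAD2 -0.95, SCARNA9 1.01, SERPINF1 0.33 and SIT1 -0.24. SLC25A37 -1.12, SNORA27 0.42, SNORA33 0.50, SNORA4 0.38, SNORA72 0.47, SNORD14A 0.74, SNORD15B 0.38 and SNORD48 0.65. SPARC 0.55, TAP1 -0.46, TLR4 -0.55, TNFAIP3 0.64, TNFAIP6 -0.55, TNFSF10 -0.62, TNNC2 0.86 and TP53RK -0.49. TRIM25 -0.61, TUT7 -0.53, UHRF1 -0.20, UQCRHL 0.32, IFI27 -0.90 and USP18 -0.18. The medians of those 2 lists, CD8 and neutrophil markers, kept their sign there. Other reversals, in lists and genes not past the threshold apart from the MHC class I and monocyte lists, were as follows. Without background correction they were -0.0090 for CD8 and cytotoxic lymphocyte markers and 0.0072 for neutrophil and granulocyte-precursor markers. With normexp without control information they were -0.0044 for CD8 and cytotoxic lymphocyte markers. With a neqc offset of 50 they were -0.00024 for CD8 and cytotoxic lymphocyte markers. With median scaling they were -0.069 for MHC class I antigen presentation (no longer past camera, adjusted p = 0.173), -0.14 for inflammatory cytokines and NF-kB targets, -0.21 for CD8 and cytotoxic lymphocyte markers, -0.13 for plasma cell and plasmablast markers, -0.11 for monocyte markers, -0.064 for cell cycle genes, -0.23 for unfolded protein and heat shock response, -0.18 for cholesterol and lipid metabolism, -0.18 for apoptosis and death receptor genes, -0.10 for KLF2 and -0.12 for PSMB10. With series matrix values on the arrays of the same ranks they were -0.0068 for CD8 and cytotoxic lymphocyte markers and 0.0064 for neutrophil and granulocyte-precursor markers. Without a filter on dim probes they were -0.0050 for CD8 and cytotoxic lymphocyte markers and -0.016 for plasma cell and plasmablast markers. With the stricter detection filter they were 0.15 for neutrophil and granulocyte-precursor markers. With the mean of probes they were -0.015 for CD8 and cytotoxic lymphocyte markers, -0.016 for plasma cell and plasmablast markers and -0.013 for cholesterol and lipid metabolism. With array weights they were 0.065 for T cell markers. Leaving out each donor moved the median or difference across 0, over ranges of -0.12 to 0.076 for T cell markers, -0.10 to 0.16 for CD8 and cytotoxic lymphocyte markers, -0.0094 to 0.071 for unfolded protein and heat shock response, -0.019 to 0.083 for cholesterol and lipid metabolism, -0.015 to 0.20 for plasma cell and plasmablast markers, -0.40 to 0.18 for neutrophil and granulocyte-precursor markers, -0.17 to 0.11 for dendritic cell markers and -0.28 to 0.12 for GNLY. Median scaling moved the median of all genes from 0.02 to -0.20. Each list and gene reversed under median scaling kept its side of that median, so its change of sign follows the shift of all genes. The cause of the other reversals was not tested, apart from the group of each array in the series matrix.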

Other observations

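In this part, the grouping of genes by symbol, the choice of the single genes named and the test of transcripts without a poly(A) tail were chosen only after the result was seen. Of 185 gene families of at least 8 tested members that share the letters of their symbol, 7 passed camera at the preset correlation, all lower in HCV, and 0 passed with an estimated correlation. Among them were both families of small nucleolar RNAs (SNORD, 49 of 51 negative, median -0.53, and SNORA, 31 of 34, -0.46) and the Cajal body RNAs (SCARNA, 8 of 9, -0.36). The others were RNU symbols (8 of 8, -0.999), spliceosomal RNAs apart from RNU105C, and histones (29 of 38, a pseudogene included, -0.33). Also among them were symbols of large-subunit ribosomal proteins (RPL, pseudogenes and paralogs included, 45 of 58, -0.10) and the small nucleolar RNA host genes (SNHG, 11 of 12, -0.27). Single members among other short RNAs ranged from RNU4ATAC (-1.80), a minor spliceosomal RNA, to RN7SK (-0.18) and RN7SL1 (0.17), the RNA of the signal recognition particle.

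Replication-dependent histone genes, whose mRNAs mostly end in a stem-loop in place of a poly(A) tail, were negative in 25 of 29 (median -0.415, against -0.09 to 0.12 in 95% of matched random gene sets), with 0 past the threshold (limma, 11 at an unadjusted p under 0.05). Histone genes were grouped by symbol, and the tail of each mRNA was not tested. Replication-independent variants, whose mRNAs mostly carry a tail, were negative in 4 of 8 (median 0.0045, quartiles -0.28 and 0.02), which leaves open whether they fell as well. A lower capture of transcripts without a poly(A) tail in the HCV samples is a candidate explanation that covers histones, spliceosomal, Y and small nucleolar RNAs alike, but it stays undecided. The value of -0.415 comes from genes picked because they fell, the variants went both ways, and RN7SK at -0.18 did not follow. RN7SL1 at 0.17 did not follow either. Its mean level of 13.64 lies near the highest value of any gene (14.59), so the signal range limits what it can show. Platelet markers, which include 1 of the 29 genes, were negative in 28 of 28 (median -0.58), and a share of platelets as the source of the histone difference was not tested. Labelling batches are not given here, and a difference between the cells of the groups was not tested.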
